A study of Mus musculus with 6 samples.

How the data were processed

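RNA was measured in kidneys of 8-week-old mice on normal chow, 3 wild-type and 3 Hspa8 knockout. Per the labels, RNA was extracted with a silica column kit and libraries were made from total RNA with a SMARTer mRNA kit. The authors deposited 1 table of FPKM per gene and library (fragments per kilobase of transcript, scaled to the mapped total), whose values are thus already divided by gene length and library total. Per the submitters' processing notes the genome builds are GRCm38 and mm10, which name the same assembly. The aligner, the quantifier, the annotation and the read type are not given in the sources used here. All 34714 gene symbols matched RefSeq's GRCm38.p6 annotation, from which the gene coordinates (1-based, whole gene) were taken.

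Samples were grouped by the genotype label and numbered as in their titles. The wild-type columns carry the strain, age and number of their titles. The knockout columns carry the letters A8 and a number, and they were assigned to the Hspa8 knockout titles of the same number because A8 ends HSPA8 and stands in no wild-type title. The letter after the age differs between the knockout and wild-type titles and not between the columns, and the age of 8 weeks was taken from the treatment label, which is the same for all 6 samples. No other column of values was left over. The labels do not say that the 3 samples of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical. No 2 libraries held identical values for any gene with a value above 0 in both.

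FPKM hold no read totals. To look for steps left by whole reads, genes under 0.1 FPKM in 2 libraries were compared, and no single ratio (in bins of 0.005 on the log2 scale) held over 0.586% of them, so no read counts were recovered and depth is unknown. No interval that needs a depth is given. A low FPKM rests on fewer reads and is less precise than a high one, and genes with a mean under 1 FPKM over the 6 libraries were left untested for that reason. Mitochondrially encoded genes are not analysed here, as 0 of their 13 listed symbols were found.

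Values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with group as the only term, an empirical Bayes variance with a trend on the mean, two-sided tests, and Benjamini-Hochberg adjustment over 12174 genes at a threshold of 0.05. A fold change is on the log2(FPKM + 1) scale, which understates the change of low genes. Means and SDs are of FPKM. Single comparisons used an exact two-sided permutation test of the difference in mean log2(FPKM + 1). Before the data were examined 35 gene lists were fixed for lipid synthesis, the series' own axis, protein quality control, metabolism, cell types of the kidney, neighbouring tissues, sex and tissue handling. Lists with at least 5 tested members, 32 of them, were tested with limma's camera at its preset correlation between genes of 0.01, with the estimated correlation of each list, and with fry, in its directional test (whether members move one way) and its mixed test (whether they move in either direction), each adjusted over the lists. With an estimated correlation camera also takes its degrees of freedom from the 6 libraries and not from the number of genes. A call can therefore be lost there without strong correlation. A member was also tested by its p adjusted over its list alone. These list-alone tests were not adjusted across the lists, so some of their calls can arise by chance. Some genes stand in more than 1 list, such as Insig1 and Srebf2 (axis and cholesterol), Srebf1 (axis and fatty acid synthesis) and Cyp4a14 (fatty acid oxidation and female-biased). Libraries were compared by principal components and Pearson correlations. Figures were drawn with matplotlib 3.10.9.

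The rule for genes named in the text was fixed before the data were examined. It takes the axis members, the 12 genes with the largest change in each direction among those that passed with groups apart (or, as none passed, the 6 with the smallest p in each direction), leaving out model names, duplicated symbols, Y-linked genes and Xist, and of each other list up to 4 members that passed or else the 2 with the smallest p. Further list members, Hbb-b1 and the genes named in the closing section were chosen after their values were seen. Values of some genes that the rule takes are not reported here, while list counts, medians and tests include them.

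The gene test and the camera test were checked on simulated data with independent noise of the observed size. With 1 list moved, camera called 1 list, the moved one. In the data the estimated correlation of the lists that camera called ran from 0.0294 to 0.821. The check therefore cannot show how camera behaves where genes are correlated. For the simulated comparison of knockout with wild-type over 12174 genes, limma called 28 of 67 genes (41.8%) changed by 0.5 on the log2 scale, 60 of 67 (89.6%) changed by 1 and 66 of 66 (100%) changed by 2, and 4 of 11974 unchanged genes. These shares depend on the independent noise and on the number of genes changed there, so they are not the power in these data. The median standard error of a log2 fold change in the data was 0.108. Alternatives were other pseudocounts, filters, scalings and variance models, the replicate number as a block, and leaving out each library. Added after the data were seen were a correction of each library for its trend with transcript length and GC content (96.6% of tested genes had a transcript) and leaving out the libraries at one end of the first component.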

Results

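RNA of 6 mouse kidney samples was profiled by sequencing, 3 from wild-type and 3 from Hspa8 knockout mice that were 8 weeks old and ate normal chow. Hspa8 encodes HSC70, the constitutive cytosolic member of the HSP70 chaperone family, which folds client proteins and strips clathrin from coated vesicles. The series asks how this chaperone bears on the release of SCAP from INSIG, on the activation of the sterol regulatory element binding proteins (SREBPs), and on the kinase PKR in kidney tubules. The comparison that these libraries give is knockout against wild-type kidney without diabetes. The wild-type titles name a strain and the knockout titles name none. Strain background, Cre and the floxed allele may therefore differ along with the knockout. Values are FPKM, fragments per kilobase of transcript scaled to the mapped total of the library, for 34714 genes, and 12174 genes with a mean FPKM of at least 1 were tested. FPKM keep no read totals, so the depth of each library is unknown. The FPKM of a library summed to between 381586 and 417123, and between 20715 and 21277 genes had a value above 0. Kap, an androgen-regulated proximal tubule transcript, took 8.02% to 10.1% of each sum.

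Hspa8 (chromosome 9, 40801276 to 40805202 in GRCm38.p6) was the gene named as deleted, and its transcript was lower in all 3 knockout libraries. It stood at 1058, 1092 and 1318 FPKM in wild-type replicates 1, 2 and 3 and at 650, 699 and 781 FPKM in knockout replicates 1, 2 and 3. The mean was 1156 ± 141 FPKM (SD, n = 3) in wild-type and 710 ± 66.0 FPKM (SD, n = 3) in knockout kidney, which left 61.4% of the wild-type level in whole tissue. The log2 fold change was -0.70 with a standard error of 0.122. An exact two-sided permutation test of the mean log2(FPKM + 1) gave p = 0.1, the smallest that 3 against 3 can give. Hspa8 ranked 4 of the 12174 tested genes by limma p, with an adjusted p of 0.866 over all genes and 0.00314 adjusted over the list alone, that list being the 15 genes of the HSPA8, SCAP, INSIG and PKR axis. The animals obtained included Hspa8-floxed and Cdh16-Cre mice, the latter carrying Cre under a promoter of kidney tubule epithelium. Cells outside the tubules, and any tubule cells in which Cre did not act, would keep the gene. Which exons are flanked by loxP sites is not given in the sources used here, and reads from exons outside the deleted part would add to these values.

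Insig1 rose in the knockout when adjusted over the axis list alone. INSIG1 is the membrane protein of the endoplasmic reticulum that retains SCAP, and Insig1 is itself a target of the SREBPs. Insig1 (chromosome 5, 28071412 to 28078662) had 13.3 ± 0.649 FPKM in wild-type and 22.5 ± 2.88 FPKM in knockout kidneys, a log2 fold change of 0.71 with a standard error of 0.107, and it ranked 2 of all tested genes (limma adjusted p = 0.866 over all genes, 0.00227 over the list alone). Srebf1 (chromosome 11, 60199084 to 60224186), which encodes SREBP1, had 8.25 ± 0.861 FPKM in wild-type and 11.4 ± 1.27 FPKM in knockout kidneys and a log2 fold change of 0.42 with a standard error of 0.109 (0.0232 adjusted over the list alone). The exact permutation test gave p = 0.1 for Insig1 and for Srebf1, the smallest it can give here, 0.2 for Srebf2 and 0.6 for Insig2. The other members did not pass over the list alone. Scap had 19.0 ± 1.30 FPKM in wild-type and 20.1 ± 1.52 FPKM in knockout kidneys, Insig2 13.0 ± 0.898 FPKM in wild-type and 14.2 ± 2.80 FPKM in knockout kidneys, and Srebf2 15.6 ± 1.32 FPKM in wild-type and 17.0 ± 0.758 FPKM in knockout kidneys. Eif2ak2, which encodes PKR, had 4.46 ± 0.140 FPKM in wild-type and 4.60 ± 0.231 FPKM in knockout kidneys, with a log2 fold change of 0.03 and a standard error of 0.0814. The log2 fold changes of Usp43, Mbtps1, Mbtps2, Nfkb1, Rela, Rnf139 and Stub1 were 0.13, -0.03, -0.06, -0.14, -0.09, -0.14 and -0.09, and none of these passed. Over all genes 0 of the 15 members passed, and adjusted over the list alone 2 rose and 1 fell. The members changed in both directions, and fry's mixed test, which asks whether a list's genes change in either direction, gave the axis an adjusted p of 0.00271, as the 1 list of 32 it called, while fry's directional test gave 0.95. Camera, which asks whether they lean one way against all other genes, gave 0.0962 (0.651 with an estimated correlation). The list was drawn from the series title and design text and holds the deleted gene, so its calls are not independent evidence. The Srebf1 call was lost without wild-type replicate 2 (0.118 over the list alone), without knockout replicate 2 (0.0807), without wild-type replicate 3 and knockout replicate 2 together (0.0664) and with the replicate number as a block (0.0674).

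**Figure D1:**
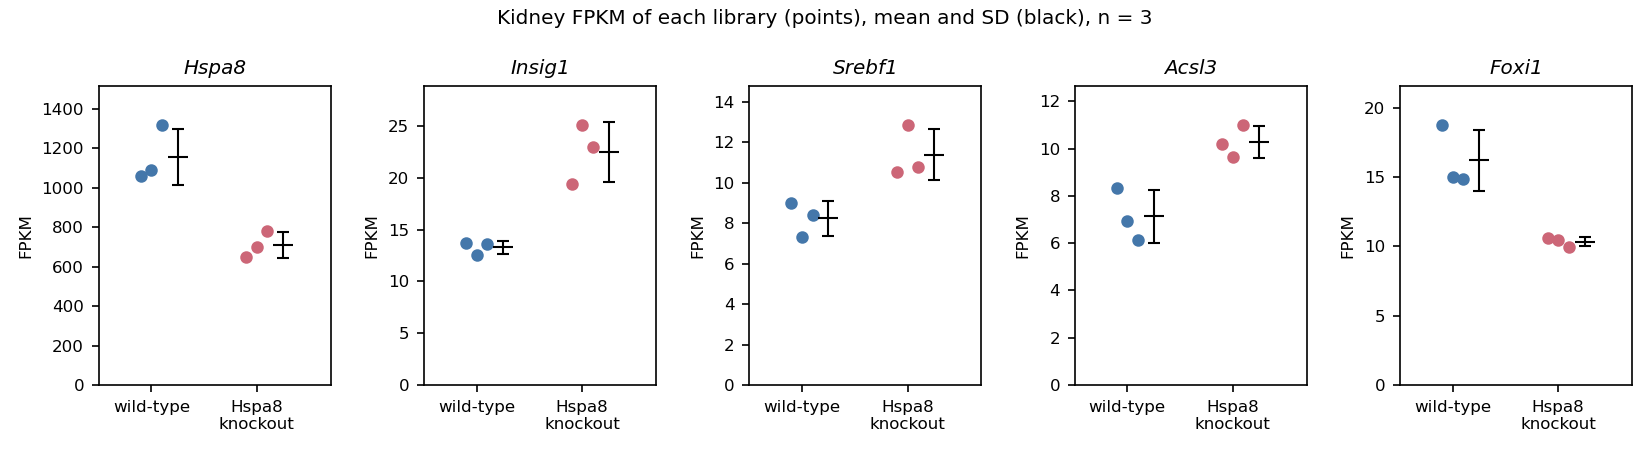
FPKM of Hspa8, Insig1, Srebf1, Acsl3 and Foxi1 in the 3 wild-type and 3 Hspa8 knockout kidney libraries, each panel on its own linear axis from 0, with points for libraries and black marks for the mean and SD. In each panel the 3 knockout points lie apart from the 3 wild-type points, as for Hspa8 with 650 to 781 FPKM against 1058 to 1318 FPKM, though no gene passed the test over all genes.

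Genes of cholesterol synthesis and uptake, the sterol-regulated targets of SREBP2, leaned higher in the knockout. Of the 26 tested members 20 had a log2 fold change above 0 and 6 below, with a median of 0.0944, a fold of 1.068. Adjusted over the list alone 2 members rose, among them Insig1 (0.00394), and 0 passed over all genes. Fdps, Msmo1, Stard4 and Dhcr7 had log2 fold changes of 0.30, 0.22, 0.21 and 0.17, while Sqle, the squalene epoxidase, had 0.09 and Idi1 -0.15, and none of these passed. The list's mean relative to all 6 libraries lay at 0.0086, -0.072 and -0.123 on the log2 scale in wild-type replicates 1, 2 and 3 and at 0.0261, 0.125 and 0.0351 in knockout replicates 1, 2 and 3. Camera with its preset correlation called the list higher (adjusted p = 1.41e-08), and the adjusted p was 0.239 with an estimated correlation and 0.525 by fry's directional test. The median fell to 0.0552 without wild-type replicate 3 and to 0.0285 without wild-type replicate 3 and knockout replicate 2, the libraries highest on the first principal component, and was 0.143 with library sums and 0.145 with library medians equalised, with the call kept in each. Over the list alone 1 member rose, Insig1, without wild-type replicate 2, knockout replicate 2, knockout replicate 3 or wild-type replicate 3 and knockout replicate 2 together, with the replicate number as a block, without a filter and with a mean of at least 5 FPKM.

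Genes of fatty acid and triglyceride synthesis, which SREBP1 drives, also leaned higher, with 18 of 25 tested members above 0 and a median log2 fold change of 0.0813. None passed over all genes or over the list alone. Acsl3, an acyl-CoA synthetase of lipid droplets, had 7.13 ± 1.11 FPKM in wild-type and 10.3 ± 0.688 FPKM in knockout kidneys and Srebf1 the values above (each 0.058 adjusted over the list alone). Each was called over this list in 6 of 19 alternatives, Acsl3 without wild-type replicate 1 (0.0176) and both with quantiles (0.0227) or medians (0.0232) equalised and with the length and GC correction (0.0151 for Acsl3, 0.0463 for Srebf1), and the adjusted p reached 0.278 without wild-type replicate 2. None of the synthetic enzymes passed: Fasn had a log2 fold change of 0.10, Acaca 0.14 and Acacb 0.20, and Thrsp, a lipogenic regulator, had -0.53. Camera called the list higher (adjusted p = 4.34e-05; 0.208 with an estimated correlation). Its median lay below 0.0813 by over 1.5 times, at 0.0527, 0.0384 and 0.0524, without wild-type replicate 2, wild-type replicate 3 or knockout replicate 3, and above it at 0.127 and 0.132 with library sums and medians equalised.

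The gene list with the smallest camera p was fatty acid oxidation and targets of PPARA, the nuclear receptor that induces lipid burning. It leaned higher, with 28 of 30 tested members above 0, a median log2 fold change of 0.156 (1.11-fold) and 7 members whose 3 knockout values all lay above the 3 wild-type values. Vnn1, the pantetheinase, had 39.9 ± 1.25 FPKM in wild-type and 51.4 ± 5.80 FPKM in knockout kidneys. Cyp4a14, a fatty acid omega-hydroxylase, had 18.7 ± 9.57 FPKM in wild-type and 56.4 ± 31.2 FPKM in knockout kidneys. Cyp4a10, of the same gene family, had 152 ± 32.4 FPKM in wild-type and 225 ± 49.5 FPKM in knockout kidneys. Pdk4, the kinase that turns off pyruvate dehydrogenase, had 13.0 ± 7.55 FPKM in wild-type and 27.0 ± 8.76 FPKM in knockout kidneys. Cpt2, a carnitine palmitoyltransferase of mitochondria, had a log2 fold change of 0.16. None passed over all genes or over the list alone, while camera called the list (adjusted p = 5.51e-14; 0.208 with an estimated correlation). The median was 0.0949 without wild-type replicate 3 and knockout replicate 2 together, with the call kept.

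Cytosolic chaperones and heat shock genes, the relatives and partners of the deleted gene, leaned lower, with 25 of 33 tested members below 0 and a median log2 fold change of -0.169. No rise of another HSP70 member passed. Chordc1, a co-chaperone of HSP90, had 30.7 ± 3.65 FPKM in wild-type and 20.8 ± 2.39 FPKM in knockout kidneys, and the HSP40 co-chaperone Dnajb1 had 28.1 ± 13.3 FPKM in wild-type and 13.6 ± 3.09 FPKM in knockout kidneys. Hsph1, Dnaja1 and Bag3 had log2 fold changes of -0.70, -0.42 and -0.49. The near-identical inducible genes Hspa1a and Hspa1b stood at 115 and 129 FPKM in wild-type replicate 3 and at 3.15 and 3.34 FPKM in knockout replicate 1, against 17.6 to 40.2 FPKM in the other libraries. No member passed over all genes or over the list alone. Camera called the list lower (adjusted p = 0.00488; 0.766 with an estimated correlation), and the call was lost without wild-type replicate 3 (0.0791, median -0.105) or knockout replicate 1 (0.133, median -0.0925). The unfolded protein and integrated stress response, with 22 of 28 members below 0, was not called (0.0791), and its members Manf and Xbp1 had log2 fold changes of -0.51 and -0.36. Lists of the other known tasks of HSC70 were not called either: lysosome and autophagy (0.775, median log2 fold change -0.0395), clathrin coat and apical endocytosis (0.36, 0.0069) and proteasome subunits (0.225, -0.0125).

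Markers of endothelium leaned lower in the knockout, with all 18 members below 0 and a median log2 fold change of -0.299 (0.813-fold). The groups did not overlap for 8 members. Pecam1, an endothelial adhesion molecule, had 13.3 ± 1.57 FPKM in wild-type and 10.1 ± 1.22 FPKM in knockout kidneys and Tek, the angiopoietin receptor, 6.06 ± 0.656 FPKM in wild-type and 4.74 ± 0.137 FPKM in knockout kidneys. Extracellular matrix and fibrosis genes also leaned lower, with 25 of 25 below 0 and a median of -0.278. The collagen gene Col3a1 had 9.94 ± 1.34 FPKM in wild-type and 6.63 ± 1.54 FPKM in knockout kidneys. Ccn2, a matrix growth factor, had 37.9 ± 11.4 FPKM in wild-type and 22.7 ± 3.01 FPKM in knockout kidneys. Interferon response genes had 26 of 28 members below 0 and a median of -0.291, with Irf9 at 8.72 ± 1.46 FPKM in wild-type and 6.29 ± 0.636 FPKM in knockout kidneys and Isg15 at log2 fold change -0.42. Immune cell markers had 13 of 14 below 0 and a median of -0.213, with Ptprc, the leukocyte antigen CD45, at 2.38 ± 0.180 FPKM in wild-type and 1.79 ± 0.123 FPKM in knockout kidneys. Podocyte and glomerular markers had 13 of 15 below 0 and a median of -0.187, with Podxl at 39.3 ± 3.43 FPKM in wild-type and 31.8 ± 4.95 FPKM in knockout kidneys. No member of these 5 lists passed over all genes or over the list alone. Camera called each of the 5 lower, with adjusted p = 2.62e-08, 3.46e-09, 1.52e-06, 0.0413 and 0.0413, and with an estimated correlation these became 0.651, 0.651, 0.651, 0.857 and 0.766. Wild-type replicate 3 stood highest for each of these lists, at 0.381 above the mean of the 6 libraries for endothelium, and for that list wild-type replicate 1 (-0.0302) lay below knockout replicate 2 (0.0226). Without wild-type replicate 3 the matrix and interferon medians were -0.170 and -0.127, and the calls of immune cells (0.642) and podocytes (0.329) were lost. The immune call was also lost without knockout replicates 1 (0.202) or 3 (0.771), and the podocyte call without wild-type replicate 2 (0.202) or knockout replicates 2 (0.52) or 3 (0.21). The immune median was -0.371 without knockout replicate 2, -0.118 without wild-type replicate 3 and -0.0637 without knockout replicate 3. The podocyte median was -0.32 without wild-type replicate 1, -0.108 without wild-type replicate 3 and -0.0912 without knockout replicate 3.

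**Figure D2:**
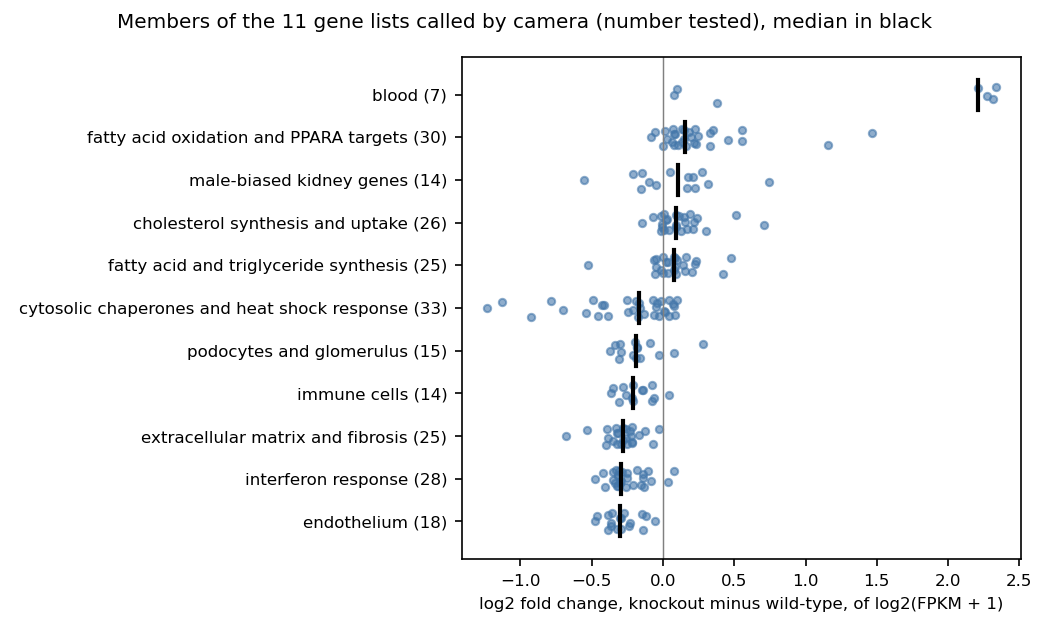
Log2 fold change of each tested member, knockout minus wild-type on the log2(FPKM + 1) scale, for the 11 gene lists that camera called with its preset correlation, with the number of tested members in parentheses and the list median as a black bar. All 18 endothelial and all 25 matrix genes lie below 0, and 28 of 30 fatty acid oxidation genes lie above it.

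Red cell transcripts were high in a pair of knockout libraries. Hba-a1, an alpha globin gene, had 15.7, 20.7 and 18.6 FPKM in wild-type replicates 1, 2 and 3 and 147, 24.4 and 186 FPKM in knockout replicates 1, 2 and 3. Hba-a2, which is near-identical to Hba-a1, and the near-identical beta globin genes Hbb-bs and Hbb-bt were also highest in knockout replicate 3. Knockout replicate 1 and then knockout replicate 2 followed. Each of these pairs of genes can share reads. Alas2, an enzyme of haem synthesis in red cell precursors, kept the same order. It had 0.33, 0.299 and 0.341 FPKM in wild-type and 1.7, 0.519 and 2.23 FPKM in knockout replicates 1, 2 and 3. Adjusted over the list alone 5 of the 7 tested members rose, among them the 4 globin genes (0.0127 each), and 0 passed over all genes. The calls of these 4 were lost with the robust variance model (0.0528 each). Camera called the blood list higher (adjusted p = 3.57e-11; 0.208 with an estimated correlation). Without knockout replicate 2 limma called 5 genes over all genes, Hba-a1, Hba-a2, Hbb-b1, Hbb-bs and Hbb-bt, all of them globin genes, and Hba-a2 then had a log2 fold change of 3.15.

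**Figure D3:**
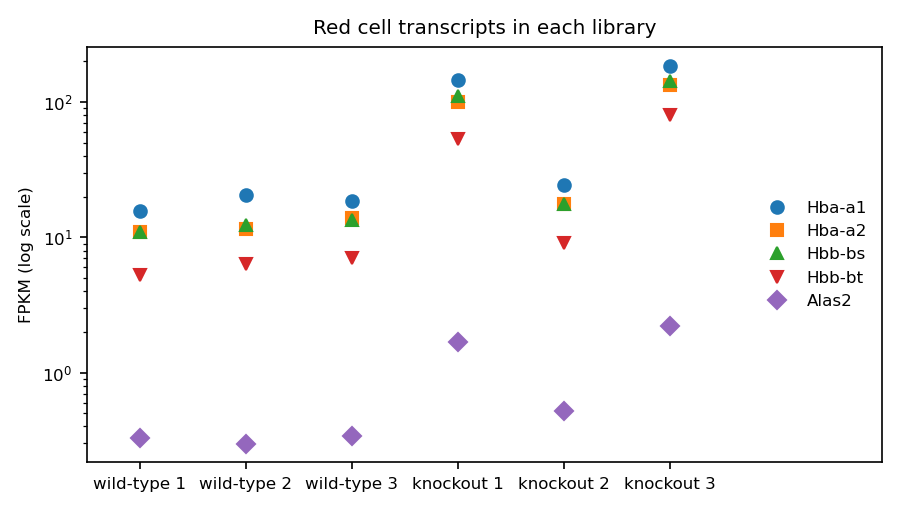
FPKM, on a log axis, of 4 globin genes and Alas2 in each of the 6 kidney libraries. Knockout replicates 1 and 3 lie above the other libraries for each gene, as for Hba-a1 with 147 and 186 FPKM against 15.7 to 24.4 FPKM.

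Markers of the tubule segments showed no list-wide lean that passed. Camera gave adjusted p = 0.0791 for proximal tubule, 0.244 for thick ascending limb, 0.449 for distal convoluted and connecting tubule, 0.609 for principal cells of the collecting duct and 0.0621 for intercalated cells, with medians of 0.0055, 0.0109, -0.0225, -0.025 and -0.0852. Foxi1 (chromosome 11, 34204341 to 34208089), the transcription factor that sets the fate of intercalated cells, fell when adjusted over the list alone (0.00664), with 16.2 ± 2.21 FPKM in wild-type and 10.3 ± 0.318 FPKM in knockout kidneys, and 0 of the other 14 members of its list passed. Gata3, a transcription factor of the collecting duct, fell over its list alone (0.0287) with 3.51 ± 0.312 FPKM in wild-type and 2.32 ± 0.277 FPKM in knockout kidneys, a call lost without wild-type replicate 1 (0.105), wild-type replicate 3 (0.104), knockout replicate 1 (0.144) or knockout replicate 2 (0.0982). It was called in 8 of 19 alternatives, with 1 in which it was not tested, and was also lost with library sums (0.0569), quantiles (0.0754) or medians (0.0505) equalised, with the replicate number as a block (0.0685), without a filter (0.0831) and without wild-type replicate 3 and knockout replicate 2 together (0.192). S100g, a calcium-binding protein of the distal nephron, had 527 ± 64.7 FPKM in wild-type and 396 ± 23.8 FPKM in knockout kidneys. Cyp27b1, the enzyme that activates vitamin D in the proximal tubule, had 0.797, 0.807 and 0.706 FPKM in the wild-type and 1.81, 1.18 and 3.13 FPKM in the knockout libraries, and neither of these passed. The proximal tubule transporters Slc13a3 and Slc22a6 had log2 fold changes of 0.22 and 0.28.

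Lists of other processes were not called in the main fit, where camera called 11 lists. Without wild-type replicate 1 camera called 16 lists, so lists outside the 11 were called there. Camera gave adjusted p = 0.357 for nuclear genes of oxidative phosphorylation, 0.449 for ribosomal proteins, 0.979 for NRF2 targets, 0.449 for tubular injury, 0.775 for NF-kB and inflammatory genes, 0.602 for immediate early genes, 0.276 for the circadian clock, 0.449 for the cell cycle, 0.775 for the glucocorticoid response and 0.583 for fat. The chemokine genes Cxcl10 and Ccl5 had log2 fold changes of -0.32 and -0.48, and the fibrinogen chain Fgg, a gene of tubular injury, -0.32. Car3, a carbonic anhydrase of adipocytes, fell over the fat list alone (0.0444) with 45.9 ± 3.89 FPKM in wild-type and 34.2 ± 5.36 FPKM in knockout kidneys, a call lost in 5 of the 6 fits that each left out 1 library, knockout replicate 1 being the exception. This call held in 8 of 19 alternatives, and was also lost with library sums (0.0649), quantiles (0.0637) or medians (0.0682) equalised, with the replicate number as a block (0.0795), without a filter (0.173) and without wild-type replicate 3 and knockout replicate 2 together (0.0647). Transcripts of the Y chromosome were present in all 6 libraries (Ddx3y 10.7 to 17.7 FPKM) and Xist lay between 0.0105 and 0.0241 FPKM. Male-biased kidney genes were called higher (0.0458; 0.764 with an estimated correlation), with 8 of 14 members above 0 and Cyp4a12a at 39.4 ± 14.0 FPKM in wild-type and 64.2 ± 11.8 FPKM in knockout kidneys, and female-biased genes were not (0.449). The male-biased call was lost without wild-type replicate 3 (0.751, where the median turned to -0.0498), knockout replicate 2 (0.0777) or knockout replicate 3 (0.261), and where library sums (0.109), quantiles (0.193) or medians (0.189) were equalised. The adrenal genes Akr1b7 and Star, the 2 tested members of that list, had log2 fold changes of -0.06 and -0.03. For 10 lists that were not called the median was below 0 while camera's direction, which is relative to all other genes, was higher: proteasome subunits, oxidative phosphorylation, NRF2 targets, NF-kB and inflammatory genes, distal convoluted tubule, principal cells, immediate early genes, circadian clock, cell cycle and glucocorticoid response. The median of all tested genes was -0.0399, and NRF2 targets (-0.0458), circadian clock (-0.054) and glucocorticoid response (-0.11) lay below that as well. The mean had another sign than the median in the distal convoluted tubule list (0.0025).

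Over all genes limma called 0 higher and 0 lower at an adjusted p under 0.05, and the smallest adjusted p was 0.866. At an unadjusted p under 0.05 there were 629 genes, 116 higher and 513 lower, where 608.7 would be reached by chance. Lower genes made up 81.6% of these, and 52.5% when library medians were equalised. The groups did not overlap for 245 genes that lay higher and 1043 that lay lower, 10.6% of those tested against 10% by chance. Of the 6 genes with the smallest unadjusted p in each direction, values are given that did not pass. On the higher side, beside Insig1, were Slc13a2, the sodium-dicarboxylate and citrate transporter (20.6 ± 2.32 FPKM in wild-type and 30.0 ± 0.992 FPKM in knockout kidneys), Ces2b, a carboxylesterase (5.25 ± 0.454 FPKM in wild-type and 7.79 ± 0.704 FPKM in knockout kidneys), Sh3tc2 (6.93 ± 0.341 FPKM in wild-type and 9.39 ± 0.115 FPKM in knockout kidneys) and Nat8f5, of a family of near-identical acetyltransferase genes (28.1 ± 6.90 FPKM in wild-type and 46.6 ± 4.42 FPKM in knockout kidneys). On the lower side, beside Hspa8 and Foxi1, were Aplnr, the apelin receptor of endothelium (2.48 ± 0.0927 FPKM in wild-type and 1.26 ± 0.0711 FPKM in knockout kidneys), Gimap4, a GTPase of immune cells (11.4 ± 0.671 FPKM in wild-type and 7.71 ± 0.314 FPKM in knockout kidneys), Fbln5, an elastic fibre protein (39.2 ± 5.51 FPKM in wild-type and 22.7 ± 3.95 FPKM in knockout kidneys), and Plpp3, a lipid phosphate phosphatase (16.5 ± 1.13 FPKM in wild-type and 12.1 ± 0.285 FPKM in knockout kidneys). With an estimated correlation, and so few degrees of freedom, camera called 0 of 32 lists. For the genotypes its preset correlation called 11 lists. In the 9 other ways of splitting the 6 libraries into 3 and 3 it called between 9 and 15. Pearson correlations between libraries over the tested genes ran from 0.979 to 0.993, the first principal component held 47.5% of the variance, and wild-type replicate 3 (23.0) and knockout replicate 2 (10.6) lay at one end of it.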

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

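The tests with the length and GC correction and without the pair of libraries at one end of the first component (wild-type replicate 3 and knockout replicate 2) were chosen after the results were seen. Over 19 alternatives the log2 fold change of Hspa8 ran from -0.77 to -0.593 (adjusted p over all genes 0.00572 to 1) and that of Insig1 from 0.631 to 0.808, and both passed over the axis list alone in 19 of 19, as Foxi1 did over its list. Srebf1 passed over the axis list in 15. Of 83 named genes 77 kept one sign, the exceptions being Akr1b7, Insig2, Mbtps1, Rela, Star and Stub1. Those outside the axis list were chosen by their p in these same libraries, so a kept sign is partly built in. FPKM without read totals limit what can be said of low genes.

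Genes called were 0 higher and 0 lower except with array quality weights (312 higher, 822 lower, Hspa8 -0.698 with adjusted p = 0.00572) and, on the higher side, without the pair at one end of the first component (5) and when each library was left out (0 to 5, the 5 globin genes without knockout replicate 2). The estimation of the weights stopped before it converged. They were 44.5 for wild-type replicate 2 and 0.225 to 2.1 for the other libraries, with 3564 genes at an unadjusted p under 0.05, so those calls rest almost wholly on 1 wild-type library. With those weights 7 lists were called in place of 11, and chaperones (0.0821), interferon (0.103), immune cells (0.184), podocytes (0.34) and male-biased genes (0.764) were lost, while immediate early genes turned to lower (0.000121).

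With an estimated correlation 0 lists were called: cholesterol 0.239, fatty acid synthesis, fatty acid oxidation and blood 0.208, matrix, interferon and endothelium 0.651, chaperones and podocytes 0.766, immune cells 0.857 and male-biased 0.764. Before adjustment 4 of these, cholesterol, fatty acid synthesis, fatty acid oxidation and blood, had p under 0.05. For fatty acid synthesis the estimated correlation was 0.0294 against the preset 0.01. Its camera p before adjustment still went from 9.50e-06 to 0.0195, as this setting has few degrees of freedom. A call lost in this setting therefore need not reflect correlation. By fry's directional test 0 were called: 0.525 for cholesterol, fatty acid synthesis, chaperones, fatty acid oxidation, matrix, interferon, endothelium and blood, 0.904 for immune cells, 0.671 for podocytes and 0.95 for male-biased genes. The male-biased call was lost with library medians subtracted (0.189), sums scaled (0.109), quantiles equalised (0.193), no filter (0.138), a mean of at least 5 FPKM (0.0507), no variance trend (0.0502) and without the pair (0.616). The podocyte call was lost with a mean of at least 5 FPKM (0.0615), the length and GC correction (0.0522) and without the pair (0.964). Without a filter the cell cycle list, not called otherwise, turned to lower (0.000723). The ranges when each library was left out were 5.56e-05 to 0.133 for chaperones, 2.67e-07 to 0.771 for immune cells, 3.31e-05 to 0.52 for podocytes, 0.00882 to 0.751 for male-biased genes and 1.66e-05 to 0.52 for immediate early genes, which were called lower without wild-type replicate 1 (0.00441) and higher without knockout replicate 1 (1.66e-05) or wild-type replicate 3 (0.000722). The cause was not tested for any of these. Cholesterol, fatty acid synthesis, fatty acid oxidation, blood, matrix and endothelium kept their direction and call with the preset correlation in every other alternative, and interferon in all but the array weights.

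With the replicate number as a block 0 genes were called higher and 0 lower, 417 had an unadjusted p under 0.05, and 12 lists were called. The deviations of same-numbered libraries from their group means correlated at 0.307, -0.215 and -0.321, so they gave no common sign of pairing by number. Wild-type replicate 3 correlated best with knockout replicate 2 (0.55). Replicate 1 of each genotype correlated best with the other (0.307), and the immediate early list lay lowest there (-1.03 in wild-type and -1.06 in knockout). A link between the replicate 1 libraries is therefore not excluded.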

Other observations

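The tests of transcript length and GC content, of cell shares and of blood RNA were chosen after the results were seen.

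Immediate early genes, which respond within minutes to handling, separated the libraries without regard to genotype. Fos stood at 1.11 FPKM in wild-type replicate 1 and 1.29 FPKM in knockout replicate 1, against 11 and 30 FPKM in wild-type replicates 2 and 3 and 26.7 and 17.9 FPKM in knockout replicates 2 and 3. Egr1 followed, with 4.13 and 6.11 FPKM in replicate 1 of each genotype and 29.8 to 43.2 FPKM in the others. The stress gene Atf3 had 0.513 and 0.566 FPKM there and 1.76 to 6.15 FPKM elsewhere. Klf2, a flow-responsive factor of endothelium in the same list, had 10.2 ± 4.57 FPKM in wild-type and 4.84 ± 1.18 FPKM in knockout kidneys. Gapdh, often used as a reference gene and one whose reads can be shared with near-identical pseudogenes, ranged from 11.7 to 66 FPKM over the 6 libraries and Actb from 189 to 278 FPKM.

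In the clock list Cry2 had 2.62 ± 0.371 FPKM in wild-type and 3.86 ± 0.746 FPKM in knockout kidneys, and Nfil3 stood at 5.4, 5.4 and 5.8 FPKM in the wild-type against 2.49, 2.02 and 5.68 FPKM in the knockout libraries. In knockout kidneys Rpl18 was the ribosomal protein gene with the smallest p (182 ± 7.24 FPKM in wild-type and 134 ± 24.9 FPKM in knockout kidneys), while 33 of 36 members of that list lay below 0 with a median log2 fold change of -0.0695. Slc22a29 of the female-biased list had 2.85 ± 0.222 FPKM in wild-type and 1.60 ± 0.686 FPKM in knockout kidneys. None of these passed over all genes or over its list alone.

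The genotypes gave 0 called genes and another split of the 6 libraries into 3 and 3 at most 1. With a count of 0 all 10 splits have as many by construction, so this comparison decides nothing, and 10 splits cannot give a share under 0.05. The split of wild-type 1 with knockout 1 and 3 gave 2290 genes at an unadjusted p under 0.05 against 629 for the genotypes, which points to a structure of the libraries other than genotype. With the preset correlation 8 of the 10 splits called as many gene lists (11 for the genotypes, at most 15).

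All 8 lists compared across splits were among the 11 that camera called for the genotypes. A small p for that split is thus partly built in, so comparing p across splits is not an independent test. Of the 8 lists, cholesterol had the widest gap between the genotypes and the other splits. Its camera p before adjustment was 1.77e-09 for the genotypes and 2.90e-04 at the smallest in another split, 1 of 10, where fatty acid synthesis had 9.50e-06 against 0.0020 and fatty acid oxidation 1.72e-15 against 4.34e-11, each also 1 of 10, the smallest share that 10 splits allow. A trend with transcript length and GC content is argued against, as the list median was 0.0993 after correction and 0.0944 before. A single library as the whole source is argued against only in that the median stayed positive when each was left out. It fell to 0.0552 without wild-type replicate 3, and to 0.0285 without wild-type replicate 3 and knockout replicate 2 together. The camera call with the preset correlation was kept after correction (adjusted p = 4.92e-08) and when each library was left out (largest adjusted p 2.70e-05). That setting called 9 to 15 lists in the other splits, so a kept call decides little. With an estimated correlation the adjusted p was 0.239, so an effect of genotype stays open, as do differences between animals or litters, which were not tested. The wild-type titles name a strain and the knockout titles do not. Differences of strain background, Cre or floxed allele between the groups would be confounded with the knockout.

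The lower endothelial and matrix lists had a camera p of 4.10e-09 and 3.24e-10 for the genotypes against 1.43e-07 and 2.57e-07 at the smallest in other splits, interferon 2.84e-07 against 7.31e-07, each 1 of 10, while for chaperones 4 of the 10 splits had a p as small (0.00122 against 3.10e-09). Length and GC correction left both calls in place (4.12e-07 for endothelium, 8.09e-08 for matrix), as did leaving out each library (largest adjusted p 0.00100 and 0.00106), all with the preset correlation, while with an estimated correlation both calls were lost (adjusted p = 0.651 each). A lower share of vascular, interstitial, immune and glomerular cells in the knockout pieces could give this, but the medians of those 4 lists, all below 0 and up to 0.112 apart, do not decide it. Abundant markers among them, Cd74 and Plvap, had 115 ± 18.0 FPKM in wild-type and 91.1 ± 22.2 FPKM in knockout kidneys and 48.9 ± 9.98 FPKM in wild-type and 34.9 ± 7.60 FPKM in knockout kidneys, and a fall of expression within these cells stays open, as does the standing of wild-type replicate 3.

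The globin genes were 8.38 (Hba-a1) to 9.68 (Hbb-bt) times higher in knockout replicates 1 and 3 than in the other libraries, and the blood list had a camera p of 2.23e-12 for the genotypes against 5.88e-12 in another split, 1 of 10. More blood RNA in those pieces is a candidate explanation that stays open. The ratio of Hba-a1 to Hbb-bs differed by at most 1.29 times over the 6 libraries, as any 1 source of both would give. The immune cell list was lowest in the same pair (-0.202 and -0.367 relative to the mean of the 6 libraries, on the log2 scale). The endothelium list was lowest there too (-0.141 and -0.316), so the immune list does not measure blood alone and does not decide. Alas2, Pf4 and Ppbp were near the floor and do not decide. Knockout replicate 2 stood near the wild-type, so a link to genotype rests on a pair of libraries and cannot be read from these data.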
